A study of Homo sapiens with 4 samples.

How the data were processed

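Expression was measured on 4 Illumina HumanHT-12 v4 bead arrays of OE33 cells, 2 transfected with a miR-223 precursor and 2 with a negative control precursor, at 10 nM and harvested after 24 h. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was amplified and labelled with biotin, and the design text calls the arrays biological replicate experiments. For single genes, limma's p-values and SE rest on the spread between these arrays, drawn toward a spread shared by all probes. The shared spread had 6.24 prior degrees of freedom, so it weighs heavily with 2 arrays in each group. For gene lists, camera p-values at the preset correlation compare genes with other genes and do not measure the spread between arrays.

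Per the file headers, the authors deposited for each array the mean bead signal of each probe as a linear intensity, with its bead standard error, the number of beads and a detection p-value. The deposited detection p-value moves in steps of 1 over 770, and was read as the share of negative control probes brighter than the probe. The quantiles of these deposited intensity values differed between arrays, so they were not quantile normalized. Their lowest signals lay between 74.3 and 81.0, and they were treated as not background subtracted. The series' value table holds deposited intensity values on a linear scale whose sorted columns differ by at most 0.23% between the 4 arrays, so they are quantile normalized by the authors. A deposited table per gene holds log2 values and a log2 fold change. For 34666 of 34666 genes checked, these deposited log2 values equalled the log2 of the mean of the quantile normalized signals over a gene's probes, to within 0.005. GenomeStudio, BeadStudio and Partek are named in the submitters' processing notes, without versions, and which step each performed is not given in the sources used here. Among the gene names deposited with the bead signals, 27 symbols were held as dates and were restored by matching values with the table per gene.

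The bead signals were background corrected by normexp on negative control values inferred from the detection p-values, with an offset of 16, quantile normalized and taken to log2 (the steps of neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.05 on at least 2 of the 4 arrays were tested, which left 18629 of 47321 probes. Differences are miR-223 minus control on the log2 scale, from limma's lmFit and eBayes with group as the only term, two-sided, adjusted over all tested probes by Benjamini-Hochberg with a threshold of 0.05. With 2 exchangeable arrays against 2, an order of the arrays as clear as the observed one arises by chance in 33.3% of probes, so no exact test of single genes was used. Normalization with an offset draws the differences of dim probes toward 0 relative to background correction with none. Relative to values without background correction, the differences of dim probes were larger, as for SYT1 (-1.09 against -0.40) and HMGB3P6 (1.14 against 0.48).

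The array's gene names were updated through a table of RefSeq genes (GRCh38.p14): 31165 probes matched a current symbol, 3263 a synonym, and 12893 kept the name in the file. No genome build is named for the probes, so no coordinates are given. For gene-level values, the probe with the highest mean intensity stands for a gene. Of 3475 genes with several tested probes, 1623 had probes of opposite sign and 34 had probes that differed by more than 1 on the log2 scale.

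The 20 gene lists were fixed before the data were examined: reported miR-223 targets, small RNA pathway, S phase, G2 and M phase, DNA repair, interferon response, NF-kB response, p53 targets, epithelial markers, mesenchymal markers, intestinal and columnar markers, squamous markers, fibroblast markers, leukocyte markers, ER stress, cholesterol synthesis, hypoxia response, immediate early genes, insulin and FOXO signalling, and ribosomal proteins. Lists with at least 5 measured members, 19 in all, were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists, and again with an estimated correlation and with fry. The reported targets were chosen from general knowledge of the literature.

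Genes were named by a rule fixed at the same time. It took genes that passed the adjusted threshold with both miR-223 arrays beyond both control arrays, the 14 with the largest fall and the 8 with the largest rise. Where fewer than 5 passed in a direction, it took the 5 with the smallest p. It added PARP1, the 4 reported targets with the smallest p and, for each other list that passed camera, the 3 members with the smallest p in the direction of the list. Genes without a symbol or with only a locus or clone name were skipped. No gene passed, so all were named by p, and 1 gene that the rule took is not reported here. NFIA, LMO2, CXCL1, NFKB2, TNFRSF12A, FOXO3, CHUK, CEBPB, HMGCS1, ANXA10, DICER1, RAD50, UBE2V1, RWDD4, HMGB3, VCF1, GAPDH, PGK1, LDHA and the metallothioneins were chosen after their values were seen.

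The fit was tested on simulated data with the spread of the real arrays: in 20 simulated sets of 18629 probes, 200 of them changed, it recovered 0.149% of probes changed by a log2 difference of 0.5, 3.21% at 1 and 84.0% at 2, with 2.75 false calls in a set. The 84.0% holds for sets with many changed probes, which ease the adjusted threshold. The list test called 2% of 100 unshifted lists of 30 genes and 97% of those shifted by 0.2. The simulated genes varied independently of each other and had no replicate effect. These shares therefore do not speak for lists whose members vary together, such as S phase (estimated correlation 0.62). The alternatives were other background correction and normalization, the authors' own values, other filters and thresholds, a variance trend, the replicate number as a block, the mean over a gene's probes, an estimated correlation and leaving out each array in turn. A test of genes that carry a miR-223 seed site in their 3' untranslated region had been planned and was not run, because it needs a reference of untranslated region sequences, not used here.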

Results

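Messenger RNA levels were measured in OE33 cells, an established line of human esophageal adenocarcinoma, after transfection with a precursor of the microRNA miR-223 or with a negative control precursor. Each precursor was used at 10 nM and cells were harvested 24 h later. Each group held 2 Illumina HumanHT-12 v4 bead arrays, which the labels describe as biological replicate experiments. The median raw signal lay between 114.5 and 118.4 intensity units, and the number of probes detected above the negative control beads lay between 18036 and 18916 of 47321. A probe signal rested on a median of 22 beads on each array. The number of arrays, 2 in each group, limits the precision of every value.

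The question was which genes differ in level when miR-223 is raised in these cells. Genes reported elsewhere as targets of miR-223 were lower as a group in the miR-223 arrays, with a median log2 difference of -0.34 over 30 measured genes. STMN1, which encodes the microtubule-destabilizing protein stathmin, and PARP1, which encodes a poly(ADP-ribose) polymerase that acts in DNA repair, had the lowest values of the list. STMN1 was at a log2 intensity of 9.49 ± 0.21 (SD, n = 2) in control cells and 8.02 ± 0.065 (SD, n = 2) in miR-223 cells, a 2.76-fold lower level. PARP1 was at 11.13 ± 0.14 (SD, n = 2) in control cells and 9.77 ± 0.018 (SD, n = 2) in miR-223 cells, a 2.57-fold lower level. For both genes the difference was larger than the spread between replicates, and both miR-223 arrays lay below both control arrays.

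Of the 42 reported targets, 30 were detected well enough to be tested, and 26 of these had a negative difference. The list passed limma's camera test (adjusted p = 7.0e-07 over 19 lists), which compares its members with all other genes. With an estimated correlation in place of the preset one, the camera p was 0.0261 before adjustment and 0.495 after, so the call did not hold there. The estimated correlation was 0.0021, below the preset 0.01, so correlation between the genes did not raise this p. That form of camera uses only the residual degrees of freedom of the 4 arrays and has little power over 19 lists. In fry, p was 0.00668 before adjustment and 0.127 after. At an unadjusted limma p under 0.05, 6 members were lower and 0 were higher. None of the 30 passed when adjusted over all probes, and 2 passed in limma, both lower, when adjusted over the list alone (STMN1 and PARP1, each at adjusted p = 0.00335). PARP1 was put on the list in the knowledge that the study followed it, so it is not independent evidence, and without it the median was -0.33. The next members by p were POLR3G, a subunit of RNA polymerase III, at -0.82 ± 0.22 (SE) on its brighter probe but -0.22 on the other, and CBFB, the beta subunit of core-binding factor, at -0.78 ± 0.25 (SE). The transcriptional regulators NFIA (-0.87 ± 0.30, SE; -0.52 without background correction) and LMO2 (-0.94 ± 0.34, SE), chosen after their values were seen, also had p under 0.05 before adjustment. Without control replicate 2 both stood at -0.52, and without miR-223 replicate 1 LMO2 stood at -0.58. FOXO3 stood at -0.37 ± 0.22 (SE), while CHUK (-0.0022 ± 0.22, SE) and CEBPB (0.12 ± 0.22, SE) showed no detectable difference. The list median was -0.22 without background correction and -0.19 without the filter on dim probes, and the list passed camera under both.

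**Figure D1:**
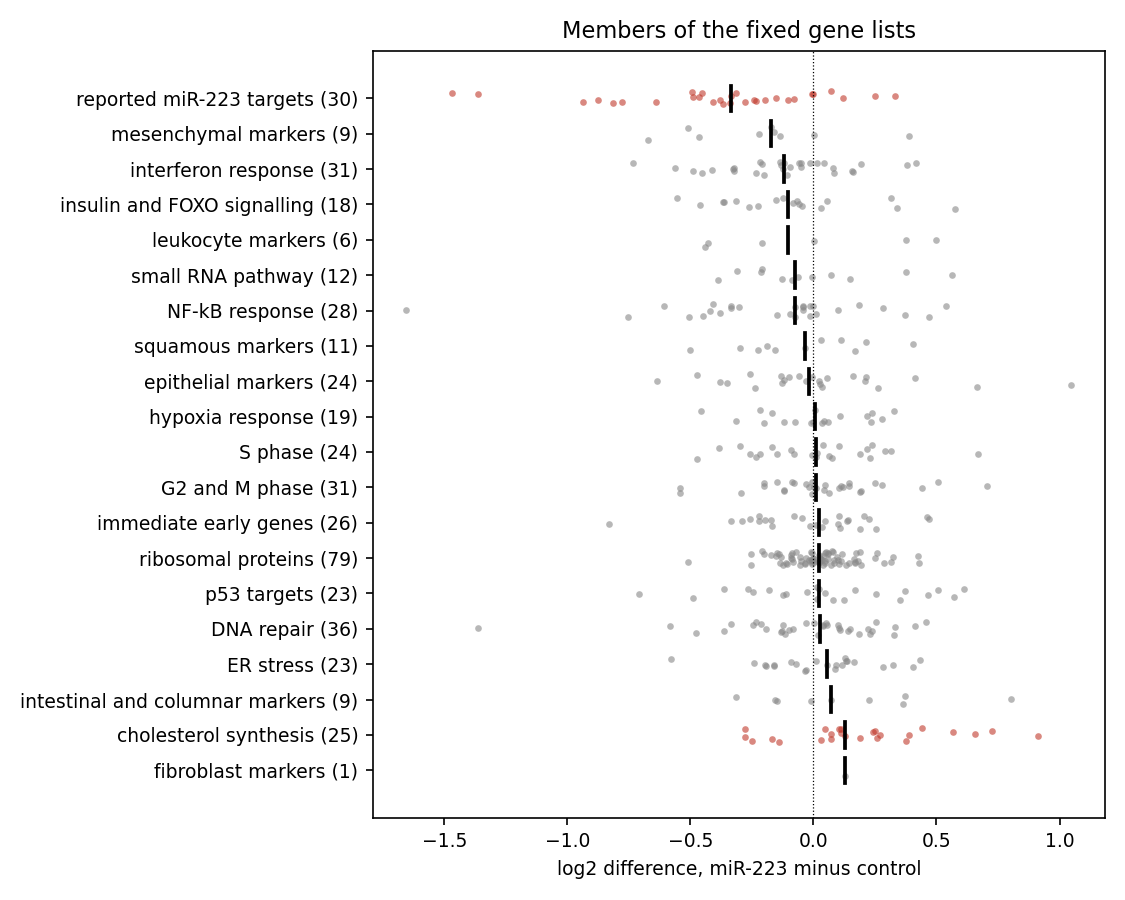
Log2 difference between miR-223 and control cells (horizontal axis) for each measured member of the 20 gene lists fixed in advance, 1 point per gene, with the number of measured members in parentheses and a black bar at the list median. Red lists passed camera with the preset correlation (reported targets, median -0.34, and cholesterol synthesis, median 0.13), and neither passed with an estimated one (adjusted p = 0.495 and 0.900).

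Across the whole array, the lower genes with the smallest p after STMN1 and PARP1 were CYB5A, SYT1 and IGSF3. CYB5A, which encodes cytochrome b5, was 2.37-fold lower (log2 -1.24 ± 0.23, SE), and a second probe gave -1.24. IGSF3, an immunoglobulin superfamily member, was 2.20-fold lower (-1.14 ± 0.23, SE), with a second probe at -1.10, and the synaptotagmin gene SYT1, a dim probe, was 2.13-fold lower (-1.09 ± 0.21, SE) but stood at -0.40 without background correction. STMN1 had a second probe at -1.08 and another, dim one at 0.57 that was detected on 0 control arrays and on both miR-223 arrays, so its probes disagreed. In the other direction, B4GALT4, a galactosyltransferase gene, was 2.58-fold higher (1.36 ± 0.24, SE), with a second probe at 0.71. MRGBP, a component of the NuA4 histone acetyltransferase complex, was 2.03-fold higher (1.02 ± 0.21, SE). The other 3 genes with the smallest p among the higher ones were pseudogenes, uncertain because their sequences are close to those of the parent genes: UBE2V1P2 at 1.11 ± 0.24 (SE), RWDD4P2 at 1.07 ± 0.22 (SE) and HMGB3P6 at 1.14 ± 0.26 (SE). Without background correction RWDD4P2 stood at 0.62 and HMGB3P6 at 0.48. The parent genes stood at 0.91 ± 0.25 (SE) for UBE2V1 (0.58 without background correction), 0.34 ± 0.23 (SE) for RWDD4 and -0.017 ± 0.22 (SE) for HMGB3. None of these genes passed the test after adjustment.

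Over the 18629 tested probes of 14224 genes, 0 passed limma at an adjusted p under 0.05, and the lowest adjusted p was 0.910. At an unadjusted p under 0.05, 1015 probes were counted, 498 higher and 517 lower, where 931 would be counted by chance. For 6181 probes, or 33.2%, both arrays of one group lay beyond both of the other, and chance gives 33.3% if the 4 arrays are exchangeable. Same-numbered arrays deviated together (correlation 0.352 across probes). They also correlated slightly more across treatments (0.987 and 0.988) than arrays of the same treatment did (0.983 for control, 0.984 for miR-223). Both values argue against exchangeable arrays, and a fit with group alone leaves this shared deviation in its error. The match of the 2 shares therefore does not show that no genes differ. Of the 6181 probes, 48 differed by at least 2-fold, 22 higher and 26 lower, among them STMN1, PARP1, CYB5A, B4GALT4 and MRGBP. Without background correction CYB5A (-0.99), B4GALT4 (0.96) and MRGBP (0.98) fell just short of 2-fold, while STMN1 (-1.20) and PARP1 (-1.28) did not. In simulated data of the same size, with 200 changed probes in a set, the test recovered 3.21% of probes changed by a log2 difference of 1. It recovered 84.0% of those changed by 2. So many changed probes ease the adjusted threshold. A lone changed probe with the median SE would need a log2 difference of 2.70. These counts come from the fit with group as its only term. With the replicate number as a block and a variance trend, fitted with limma's robust option and combined after seeing the data, limma called 176 probes. Among them were PARP1 (adjusted p = 3.9e-05) and STMN1 (adjusted p = 5.4e-05). The block alone called 0 probes on these values. A block leaves fewer residual degrees of freedom than group alone, so the blocked p-values lean more on the spread shared by all probes. The labels do not say that a number marks a shared experiment. In the authors' deposited table of log2 fold changes, PARP1 had the lowest value of 34693 genes (-1.28), followed by the metallothionein gene MT1E (-1.19) and the cytokine receptor gene TNFRSF12A (-1.15). MRGBP had the highest (0.98) in the authors' deposited table, where 4 genes were lower by at least 2-fold and 0 were higher. That table averages a gene's probes, and for the named genes the authors' probe values lie near those without background correction. Its counts are therefore not comparable with the 48.

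**Figure D2:**
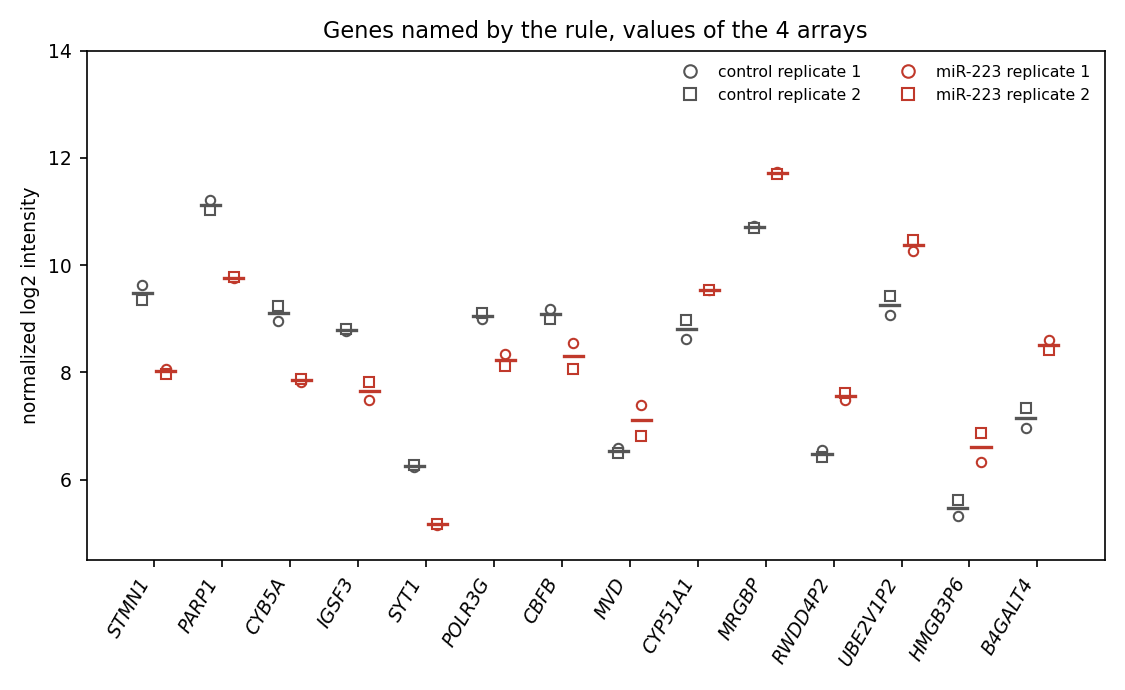
Normalized log2 intensity (vertical axis) of 14 genes named by the fixed rule on each of the 4 arrays, grey for control and red for miR-223, circles for replicate 1 and squares for replicate 2, with lines at the group means. PARP1 moves from a mean of 11.13 to 9.77 and MRGBP from 10.71 to 11.73. None of the genes passed after adjustment over all probes in the fit without a replicate block.

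Genes of cholesterol synthesis and uptake were slightly higher as a group in the miR-223 arrays, with a median log2 difference of 0.13 over 25 measured genes, 20 of them with a positive difference. CYP51A1, the lanosterol demethylase, stood at 0.72 ± 0.23 (SE), from 8.81 ± 0.25 (SD, n = 2) in control cells to 9.53 ± 0.0015 (SD, n = 2) in miR-223 cells. MVD, an enzyme of the mevalonate pathway, stood at 0.57 ± 0.26 (SE), at 0.32 without background correction, at 0.28 without miR-223 replicate 1 and at 0.86 without miR-223 replicate 2. HMGCS1, which encodes a synthase of the same pathway, was at -0.25 ± 0.23 (SE). The list passed camera in limma (adjusted p = 0.0257 over 19 lists), but the adjusted p was 0.900 with an estimated correlation. For this list the estimated correlation was 0.0799, above the preset 0.01. The p at the preset correlation may therefore be too small, unlike for the reported targets. None of the list's members passed limma when adjusted over all probes or when adjusted over the list alone, and 1, CYP51A1, had p under 0.05 before adjustment. Without control replicate 1 the camera adjusted p was 0.254 with a median of 0.14, and without miR-223 replicate 2 it was 0.475 with a median of 0.11.

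None of the other 17 lists tested with limma's camera passed, and fry in limma called 0 of the 19 lists after adjustment. Among the inflammatory genes of the NF-kB list, 21 of 28 had a negative difference and the list median was -0.075 (camera adjusted p = 0.181). The chemokine gene CXCL1 had the lowest value, 3.15-fold lower at -1.66 ± 0.36 (SE), and was the 1 member that passed in limma when adjusted over the list alone (adjusted p = 0.0446), with 0 passing over all probes. CXCL1 was at 7.68 ± 0.75 (SD, n = 2) in control and 6.02 ± 0.35 (SD, n = 2) in miR-223 cells, and its difference was -0.93 without background correction. NFKB2 stood at -0.76 ± 0.25 (SE) on its brighter probe, or -0.50 without miR-223 replicate 1, and -0.49 on the other probe. Interferon response genes had a median of -0.12 (adjusted p = 0.449), and mesenchymal markers, with 9 measured, a median of -0.17 (adjusted p = 0.157). Among DNA repair genes, PARP1 was the 1 of 36 that passed in limma when adjusted over the list alone (adjusted p = 0.00805), RAD50 stood at -0.58 ± 0.22 (SE), and the list median was 0.028 (camera adjusted p = 0.953). DICER1, which encodes a microRNA-processing enzyme, stood at 0.56 ± 0.21 (SE) on its brighter probe and 0.63 on the other, in a small RNA pathway list with a median of -0.075 (adjusted p = 0.953).

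Genes of the cell cycle showed no detectable shift as groups, with medians of 0.012 for S phase (camera adjusted p = 0.953) and 0.012 for G2 and M phase (adjusted p = 0.930) in limma. Epithelial markers had a median of -0.018 (camera adjusted p = 0.953), with 2 members higher and 1 lower at an unadjusted limma p under 0.05. Intestinal and columnar markers had a median of 0.069 (adjusted p = 0.516), with ANXA10 at 0.80 ± 0.23 (SE), or 0.45 without background correction, and squamous markers a median of -0.034 (adjusted p = 0.953). Leukocyte markers, with 6 measured, had a median of -0.10 (adjusted p = 0.953), and 1 fibroblast marker was measured, at 0.13. The medians were 0.023 for p53 targets (adjusted p = 0.873), 0.053 for ER stress (adjusted p = 0.953), 0.0043 for the hypoxia response (adjusted p = 0.953) and 0.022 for immediate early genes (adjusted p = 0.953). Insulin and FOXO signalling had a median of -0.10 (adjusted p = 0.562) and the ribosomal proteins, with 79 measured, a median of 0.023 (adjusted p = 0.930). In the DNA repair, hypoxia and immediate early lists the median was positive while the mean and the camera direction were negative, and in the epithelial list the mean alone was positive. With an estimated correlation, 0 of the 19 lists passed.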

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

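Combinations of the replicate block or of other values with other settings, and the reported targets without PARP1 or STMN1 were chosen after seeing the data. With limma, 0 probes passed under every planned normalization, filter and variance model, with the replicate block alone, and at an adjusted p under 0.1 or with a 1.5-fold minimum; at an unadjusted p under 0.05, 1015 were counted. Leaving out 1 array, with a lone array assumed to vary like the other group, gave 0 to 1 probes, all lower: without control replicate 2, VCF1 passed at -4.19 (limma adjusted p = 0.0255), against -1.69 on all 4 arrays, where it did not pass. The labels do not say that a replicate number marks a shared experiment. Deviations of same-numbered arrays from their group means correlated at 0.352 across probes, and the replicate block left the counts at 0 probes and 2 lists. In all, 20 combinations of values, variance model and block were fitted: the 10 without the block called 0 probes, and 7 of the 10 with it made calls, so these calls rest on the block. The replicate block with a variance trend called 176 probes (69 higher, 107 lower) on the main values, among them PARP1 (adjusted p = 3.9e-05) and STMN1 (adjusted p = 5.4e-05), 346 (162 higher, 184 lower) without background correction, 204 (84 higher, 120 lower) after cyclic loess, 202 (110 higher, 92 lower) after median scaling and 397 (185 higher, 212 lower) on the authors' values. The replicate block alone called 357 (166 higher, 191 lower) without background correction and 402 (189 higher, 213 lower) on the authors' values. The variance trend was always fitted with limma's robust option. With the block, fewer residual degrees of freedom are left than with group alone. These p-values therefore lean more on the spread shared by all probes. The cause of the calls was not tested.

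The reported targets kept their direction and passed camera in every setting except the estimated correlation (median -0.34, adjusted p = 0.495), with medians from -0.34 to -0.24 when 1 array was left out and -0.32 without PARP1 and STMN1; the lowest adjusted p was 2.2e-08. The cholesterol genes kept their direction, with a lowest adjusted p of 0.00218, did not pass with an estimated correlation (median 0.13, adjusted p = 0.900), and had medians from 0.11 to 0.21 when 1 array was left out, not passing without control replicate 1 or miR-223 replicate 2; the cause was not tested. The number of lists that passed was 0 with an estimated correlation and 2 to 4 when 1 array was left out. Without miR-223 replicate 1, immediate early genes turned to a median of -0.20 and passed (adjusted p = 0.0409), and their medians reached 0.24 when other arrays were left out; the cause was not tested. Interferon response genes passed without control replicate 1 or without miR-223 replicate 2 (median -0.33 in both), NF-kB genes without control replicate 2 and mesenchymal markers without miR-223 replicate 1. The planned test of seed-site genes and its alternatives were not run.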

Other observations

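The tests of the metallothioneins and of the reported targets without STMN1 and PARP1 were chosen after the values were seen, and the metallothionein and glycolysis lists were picked after several gene families had been looked through. Genes of metallothioneins, small proteins that bind zinc and copper, were among the lower ones in the miR-223 arrays. MT1E stood at -1.27 ± 0.29 (SE), 2.41-fold lower, MT1G at -0.92 ± 0.27 (SE), or -0.43 without background correction, and the related pseudogenes MT1IP and MT1P3 at -0.93 ± 0.26 (SE) and -0.69 ± 0.25 (SE). Without miR-223 replicate 1, MT1P3 stood at -0.44. MT2A (-0.17 ± 0.24, SE), MT1X (-0.17 ± 0.24, SE) and MT1A (-0.26 ± 0.24, SE) differed by no more than about their error, and MT1F stood at 0.16 ± 0.24 (SE). The signs of MT2A, MT1X and MT1F turned when 1 of the miR-223 arrays was left out. The receptor gene TNFRSF12A stood at -1.19 ± 0.24 (SE), 2.27-fold lower. None of these genes passed limma after adjustment over all probes. Camera on the 8 measured metallothioneins gave p = 3.1e-05 with a preset correlation and p = 0.154 with an estimated one, on a list built after the values were seen. Near-identical family members can bind each other's probes, which was not tested.

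The lower level of the reported targets was weighed against technical explanations. A shift that depends on brightness is argued against, since 0.0001 of 10000 random lists matched on mean intensity had a median as low, the smallest share they can give. Without STMN1 and PARP1 the list gave a camera p of 6.6e-06, so these members alone do not carry it. A direct effect of the transfected miR-223 on its targets is a candidate explanation, but the seed-site test was not run. The list also did not pass camera with an estimated correlation (adjusted p = 0.495), where the 4 arrays leave little power. A difference between the arrays that happened to follow the treatment stays open, with 2 arrays in each group. The other 2 ways to split the 4 arrays into pairs gave list medians of -0.069 (by replicate number) and 0.081 (crossed), smaller in size than the -0.34. Treatments cancel in these splits, so they cannot exclude an array difference that followed the treatment.

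The shift of the cholesterol genes stays undecided. With the number as a block the list passed camera with the preset correlation (adjusted p = 0.0337), but without the block it did not pass with an estimated one (adjusted p = 0.900), nor without control replicate 1 (adjusted p = 0.254) or miR-223 replicate 2 (adjusted p = 0.475). The other 2 splits of the arrays, in which treatments cancel, gave list medians of -0.18 (by replicate number) and -0.046 (crossed). The first is larger in size than the 0.13, so a shift of that size also arose between arrays apart from treatment. A share of 0.02 of random lists matched on brightness had a median as high, which leaves a brightness-dependent shift open. An effect of miR-223 itself was not tested apart from these and stays open.

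Common reference genes were uneven between their own probes. GAPDH stood at 0.065, -0.49 and -0.16 on its 3 probes, PGK1 at -0.46 and 0.067, and LDHA at -0.32, 0.22 and 0.16. If the lower probes may reflect lower glycolysis transcripts as a group, the other enzymes should be lower too, but the 17 others had a median of 0.02 (from -0.40 to 0.37; camera p = 0.827), a median that was -0.0075 without background correction and -0.0079 on the authors' values.

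The probe annotated to MIR223 was detected on 0 of the 4 arrays. The arrays give no direct reading of the transfected microRNA, so the labels' treatment could not be checked by it. Across probes, the difference between replicate numbers was wider than that between treatments, with an SD of 0.341 against 0.285 on the log2 scale. By at least 1.5-fold, 1551 probes differed between the numbers against 885 between the treatments. The crossed split, in which treatments and numbers both cancel, was narrower than either, with an SD of 0.236 and 432 probes.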
